A study of Mus musculus with 2 samples.

How the data were processed

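Polyadenylated RNA was sequenced from inflammation-experienced regulatory T cells of an adult male mouse of 6 months, of a strain that carries a Foxp3-driven CreERT2 recombinase and a Rosa26 YFP reporter. Regulatory T cells are CD4 T cells that restrain immune responses and are defined by the transcription factor Foxp3. The labels gave 1 group with 1 biological replicate, sequenced as 2 technical libraries with sheared fragments of 100 to 300 bp. No control or untreated cells were analysed here, so no comparison between conditions could be made. The measurements were the level of each gene, its spread over the technical libraries, and the comparison of these libraries with each other. The SD covered technical variation and not the variation between animals.

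For each library a larger gene table, a transcript table and a smaller gene table were used. The larger gene table held estimated counts, posterior mean counts, TPM and FPKM that the authors deposited, per the file headers. It covered mouse genome mm10 with GENCODE M21 genes plus transfer RNA, ERCC spike-in and phiX174 entries. TPM was scaled by the authors to a fixed sum over all of these entries. Credibility bounds of TPM, which the authors deposited beside it and which were recorded as signal values because their sum is not fixed as that of TPM is, were not used for any result. The transcript table held estimated counts, TPM and the percent of a gene's TPM assigned to each transcript, as deposited. The smaller gene table held whole-number counts, which the authors made from genome alignments with GENCODE M4 genes, per the text deposited with each library. Aligner, quantifier, strand setting and versions were not given in the sources used here. In the larger table the effective length was 49 nt shorter than the gene length for 99.99% of entries. Of the non-zero estimated counts, 59.8% were whole in technical replicate 1 and 59.3% in technical replicate 2, with a tolerance of 0.005. The others came from reads divided between genes by estimation, which makes paralogs, pseudogenes and overlapping genes uncertain.

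Annotated genes took 99.83% and 99.84% of the estimated counts in technical replicates 1 and 2. Entries without a gene name were kept out of library sizes and tests. The phiX174 entry took 0.157% and 0.142% of the counts, the transfer RNA entries 0.0170% and 0.0168%, and the ERCC entries 0 counts. Gene totals were 15386113 and 13604480 rounded counts in the larger table. The smaller table held 3581589 and 3271045 counts over 22457 genes, of which 22195 had an identifier in the larger table. A count of 3, the most that a count of 0 allows, came to 0.195 and 0.221 CPM. Intervals and this limit covered counting error only, since reads without molecular identifiers are not independent molecules.

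A total of 24 gene lists were fixed before the data were examined. They covered T cell identity, regulatory T cell identity and function, effector and resting states, helper cytokines, chemokine receptors, interferon-stimulated genes, immediate early genes, proliferation, chromatin regulators, Foxp3 partner factors and interleukin-2 signalling. Another 9 lists held markers of other cell types, and the remaining lists held sex-linked and housekeeping genes. A member was called detected at 1 TPM or more in both libraries. The median TPM of a list was placed among 10000 random lists of the same size, drawn from genes with a read in either library. For ratios between the libraries, log2((TPM + 1) in technical replicate 2 over technical replicate 1), the random lists were matched on mean expression in 20 bins. No p-value was computed for lists.

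Estimated counts were rounded to whole numbers for the test between the technical libraries. This was a two-sided exact binomial test per gene with at least 10 counts summed, with the expected share from TMM effective library sizes (edgeR 4.0.16) and Benjamini-Hochberg adjustment at 0.05. The test compared these 2 libraries and no conditions, and it assumed that only the sampling of reads separated them. edgeR was also used to fit a common dispersion with an intercept only, which gave a coefficient of variation of 0.105 for the larger and 0.0749 for the smaller table. The binomial test was tested on simulated Poisson counts for the comparison of technical replicate 2 with 1. Over 17356 genes it made 4 false calls and recovered 58.6% of genes changed 2-fold and 80.4% of those changed 4-fold, none with the wrong sign. These counts held read sampling alone, as the test assumes. The measured libraries differed by more (index of dispersion 4.98), so the simulation gives no rate of false calls for them. Of 200 simulated lists without a shift, 5% fell outside the central 95%, with values drawn independently for each gene.

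Shares of T cell receptor V segments were computed from rounded counts with 95% Clopper-Pearson intervals. The gene tables were compared by each gene's share of the counts of matched genes, and a gene was called discordant when the shares differed over 4-fold in both libraries with at least 50 counts in the higher table. The text names, of each list, up to 6 members with the highest mean TPM and up to 6 below the detection threshold. It also names the 15 most abundant genes other than ribosomal protein and mitochondrial genes, the 5 genes per direction with the largest called ratio between the libraries at 100 or more counts, and the 3 most discordant genes per direction between the tables. The 3 most used Trbv and Trav segments and 12 genes fixed for isoforms complete the rule. Some genes that the rule covers are not reported here. Other genes named were chosen after their values were seen.

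Alternatives changed the TPM threshold, unit, pseudocount, normalization (DESeq2 1.42.0 size factors or raw totals), filter, test, random lists and gene table, or left out each library. The alternatives on parts of the smaller table, the list ratios in it and those on marker lists without genes known in T cells were chosen after the data were seen. Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. Gene positions were those of GENCODE M21 on mm10.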

Results

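The polyA RNA of inflammation-experienced regulatory T cells was measured in 2 technical libraries of 1 biological replicate. Technical replicate 1 held 15386113 gene counts and technical replicate 2 held 13604480. Values are the mean TPM ± SD over the technical libraries (n = 2) unless the libraries are given apart. An SD over 2 libraries can fall below the counting error, so a small SD does not show that a level is known that closely. The median of a gene list is taken over the mean TPM of its members, and its ± is the SD between the medians of the libraries, whose mean can differ from it. With 1 animal group and no reference population, levels describe these cells and show no change caused by inflammation.

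To define the transcriptome of these cells, genes at 1 TPM or more in both libraries were counted. These were 13511 genes, of which 10288 were protein coding, 309 were lincRNA genes and 1251 were pseudogenes. Another 2307 genes reached the threshold in only 1 library. The cytoskeletal actin gene Actb (chromosome 5, 142903115 to 142906754, minus strand) was the most abundant named gene, at 39106 and 37907 TPM. It was followed by the ribosomal RNA gene CT010467.1 (9275 and 11755 TPM), the actin-binding peptide gene Tmsb4x (9528 and 9509 TPM), the nuclear lincRNA Malat1 (9066 and 8189 TPM), the elongation factor gene Eef1a1 (7700 and 7985 TPM) and the MHC class I light chain gene B2m (6350 and 6539 TPM). The polyubiquitin gene Ubb (4296 and 4018 TPM), the MHC class I genes H2-K1 (4021 and 4271 TPM) and H2-D1 (3250 and 3331 TPM), and the T cell receptor constant gene Trbc2 (3803 and 3725 TPM) also belonged to the 15 highest. The other 5 were AY036118, Gm37376, Gm10925, Rps23-ps1 and Gm12918. AY036118 lies within CT010467.1 and Gm37376 within Malat1 on the other strand, and Gm10925, Rps23-ps1 and Gm12918 are annotated as pseudogenes. The levels of these 5 may depend on how reads were divided between overlapping genes or copies, which was not tested. Ribosomal protein genes took 7.29% and 7.39% of gene counts, and mitochondrial genes 3.72% and 3.65%. Nuclear ribosomal RNA genes took 1.35% and 1.70%.

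T cell and regulatory T cell genes were uniformly detected. All 18 members of the T cell core list reached 1 TPM in both libraries, with a median of 371.6 ± 0.86 TPM. Its highest members were the receptor constant gene Trac (2998 ± 48.0 TPM), the receptor-proximal kinase gene Lck (1228 ± 83.3 TPM) and the CD3 chain gene Cd3g (1154 ± 14.3 TPM). The 19 regulatory T cell identity genes were all detected too, with a median of 171.1 ± 9.34 TPM. The folate receptor family gene Izumo1r (1050 ± 14.98 TPM), the co-stimulatory receptor genes Tnfrsf4 (499.9 ± 11.5 TPM) and Tnfrsf18 (456.5 ± 25.6 TPM), and the transcription factor gene Ikzf2 (425.7 ± 0.46 TPM) led this list. Of the Ikzf2 TPM, 62.3% was assigned to a short retained-intron transcript, so the rank of Ikzf2 depends on that assignment. The protein-coding Ikzf2-201 held 128 and 121 TPM. The inhibitory receptor gene Ctla4 reached 171.1 ± 14.0 TPM and the high-affinity interleukin-2 receptor gene Il2ra 174.9 ± 0.73 TPM. Foxp3 itself (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand) stood among the lower members at 19.98 ± 2.93 TPM, from 411.8 and 325.0 estimated counts. Of the Foxp3 TPM, 81.4% was assigned to the 1557 nt transcript Foxp3-207, so this level depends on that assignment. Whether the engineered Foxp3 allele of the strain affected the level was not tested. The medians of the T cell core and identity lists lay at the 100th percentile of random lists. So did those of the housekeeping, chromatin regulator and chemokine receptor lists, so this rank is not particular to T cell genes. Over all 24 lists, 14 medians lay above the central 95% of random lists, and 8 when the random lists were drawn from genes at 1 TPM or more.

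Effector and resting regulatory T cell genes were present together. Of the 25 effector genes 24 were detected (median 69.6 ± 2.61 TPM), and all 15 resting or central genes were (median 131.1 ± 7.02 TPM). The activation marker gene Ly6a (374.6 ± 1.63 TPM), the transcriptional regulator gene Id2 (308.7 ± 0.035 TPM), and the receptor genes Tigit (260.5 ± 2.99 TPM), Icos (254.2 ± 18.7 TPM) and Pdcd1 (193.6 ± 4.43 TPM) were, with the calcium-binding protein gene S100a6, the highest effector members. Havcr2, an inhibitory receptor gene, was the member below threshold, at 1.72 and 0.89 TPM. Among the resting genes, the transcription factor genes Tcf7 (296.3 ± 1.55 TPM) and Id3 (217.5 ± 2.17 TPM) and the lymph node homing gene Ccr7 (206.3 ± 9.88 TPM) were among the highest. The suppressive function list had a median of 33.7 ± 0.84 TPM with 13 of 14 members detected. Lgals1 (328.9 ± 1.55 TPM), the adenosine-producing ectoenzyme gene Nt5e (218.3 ± 10.6 TPM) and Entpd1 (38.9 ± 2.04 TPM) were among its highest, whereas the anti-inflammatory cytokine gene Il10 reached 5.61 ± 0.47 TPM. Il12a had no read in either library.

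Interleukin-2 signalling genes were all detected (14 of 14, median 67.9 ± 2.28 TPM), led by the receptor genes Il2rg (1285 ± 31.3 TPM) and Il2rb (322.7 ± 17.5 TPM) and the kinase gene Jak1 (287.4 ± 15.8 TPM). Chromatin regulators (22 of 22, median 27.6 ± 0.47 TPM) were led by the histone deacetylase genes Hdac1 (190.2 ± 12.1 TPM) and Hdac7 (57.6 ± 0.52 TPM). Foxp3 partner factors had 23 of 24 members detected (median 33.6 ± 0.35 TPM), led by Ets1 (608.9 ± 31.4 TPM) and Ikzf2, with Eomes below threshold at 0.46 and 0.70 TPM. Chemokine receptor and homing genes had 22 of 24 detected (median 76.8 ± 3.24 TPM). The selectin ligand gene Selplg (365.4 ± 23.0 TPM), the integrin gene Itgb7 (319.1 ± 32.5 TPM) and the type 1 chemokine receptor gene Cxcr3 (136.8 ± 8.25 TPM) were among the highest, and Ccr3 and Ccr10 were below threshold. Interferon-stimulated genes had 21 of 22 detected (median 25.1 ± 0.52 TPM), with the guanylate-binding protein gene Gbp4 at 178.0 ± 2.13 TPM among the highest. Oas2 was below threshold at 0.53 and 0.54 TPM.

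Helper cytokine genes were low. Their median was 0.455 TPM, but 0.86 TPM in technical replicate 1 and 0.37 TPM in technical replicate 2, and 5 of 13 were detected, namely Tnf (15.9 ± 0.40 TPM), Il4 (11.8 ± 1.20 TPM), Ifng (9.36 ± 2.09 TPM), Il21 (7.11 ± 1.83 TPM) and Il2 (2.31 ± 0.21 TPM). Csf2 stood at 0.86 and 0.85 TPM, and Il17f, Il17a and Il5 were also below threshold. Il13, Il22, Il9 and Il3 had no read in either library, which allows up to 0.195 and 0.221 CPM. Proliferation genes had 19 of 20 members detected at a median of 7.61 ± 2.48 TPM, with the replication genes Pcna (106.9 ± 5.71 TPM) and Mcm6 (71.2 ± 2.79 TPM) highest. The checkpoint kinase gene Bub1 was below threshold in technical replicate 2, at 1.21 and 0.58 TPM. Immediate early and stress genes had 15 of 19 detected (median 24.5 ± 3.64 TPM), led by the NF-kappaB inhibitor gene Nfkbia (438.6 ± 28.1 TPM) and the antiproliferative gene Btg2 (158.2 ± 8.55 TPM). Fosb, Hspa1a, Hspa1b and Atf3 were below threshold.

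**Figure D1:**
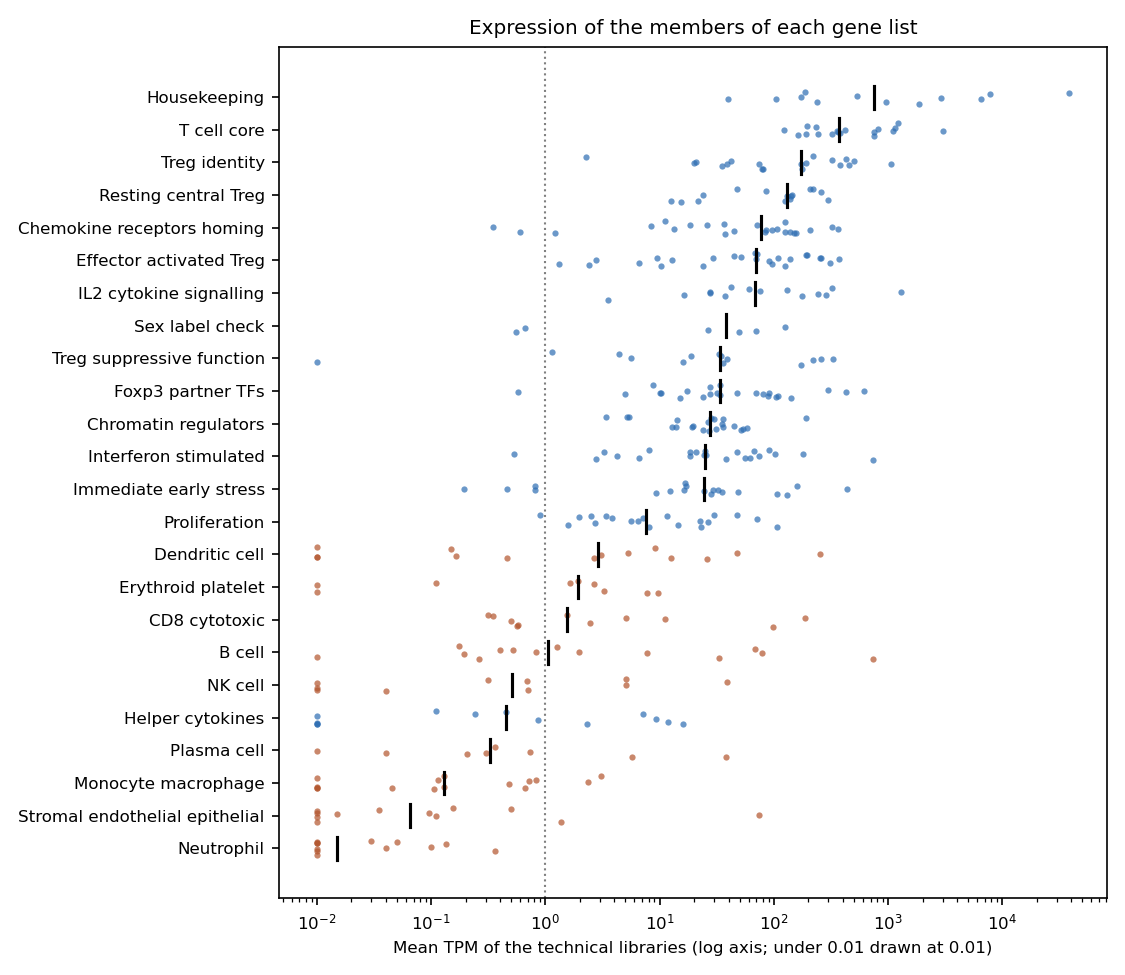
Each point is a gene, placed by its mean TPM over the technical libraries (log axis), with 1 line of points per gene list, lists of other cell types in brown and the rest in blue. Black bars are list medians, which range from 0.015 TPM for neutrophil markers to 371.6 TPM for the T cell core and 748.2 TPM for housekeeping genes, and the dotted line marks 1 TPM.

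To measure RNA of other cells, 103 marker genes on 9 lists were examined. Of these, 34 reached 1 TPM in both libraries and 23 had no read in either. Neutrophil markers had a median of 0.015 TPM (0 and 0.015 TPM in technical replicates 1 and 2) with 0 of 12 detected, and S100a8 and S100a9 stood at 0.10 and 0.36 TPM on average. Stromal, endothelial and epithelial markers (median 0.065 ± 0.0035 TPM, 2 of 12 detected), monocyte and macrophage markers (0.130 ± 0.035 TPM, 2 of 15), plasma cell markers (0.330 ± 0.021 TPM, 2 of 8) and NK cell markers (0.505 ± 0.23 TPM, 3 of 10) also had medians under 1 TPM. B cell (1.05 ± 0.17 TPM, 6 of 14), CD8 and cytotoxic (1.56 ± 0.22 TPM, 6 of 11), erythroid and platelet (1.91 ± 0.30 TPM, 6 of 9) and dendritic cell lists (2.86 ± 0.17 TPM, 8 of 14) lay above it. The T cell core median was 371.6 TPM. The immunoglobulin heavy chain gene Ighm reached 741.6 ± 49.8 TPM and the B cell genes Igkc 68.3 ± 48.1, Cd79b 33.1 ± 4.85 and Cd22 7.77 ± 2.00 TPM, whereas Cd79a (1.27 ± 0.55 TPM) and Ms4a1 (0.515 ± 0.26 TPM) did not reach 1 TPM in both libraries. The invariant chain gene Cd74 reached 254.8 ± 15.5 TPM, with its MHC class II partner genes H2-Eb1 at 9.10 ± 2.98 TPM and H2-Aa at 5.26 ± 2.41 TPM. Ccl5 (186.3 ± 6.65 TPM), Nkg7 (99.0 ± 0.43 TPM), Pecam1 (74.6 ± 0.042 TPM), Cd72 (77.8 ± 0.94 TPM), Txk (38.9 ± 0.049 TPM) and Xbp1 (37.9 ± 2.07 TPM) were high members of the remaining lists, and the highest monocyte and macrophage markers were Cd68 (3.04 ± 0.45 TPM) and Cebpb (2.35 ± 0.042 TPM). The pore-forming protein gene Prf1 (5.12 ± 0.93 TPM), the CD8 chain gene Cd8b1 (11.2 ± 0.30 TPM) and Epcam (1.38 ± 0.057 TPM) were also detected. Members below threshold included Fcer2a, Pax5 and Blk (B cells), Mzb1, Derl3, Igha, Sdc1, Ighg1 and Tnfrsf17 (plasma cells), Gzmm, Klrd1, Klrk1 and Gzma (cytotoxic cells), and Khdc1a, Klrb1c, Klra4, Ncr1 and Klre1 (NK cells). They also included Tyrobp, Lyz2, C1qb, Fcgr3, Fcer1g and C1qa (monocytes and macrophages), Ltf, Ly6g, Ngp and Cxcr2 (neutrophils), Xcr1, Siglech, Clec9a, Flt3, Itgax and Cd209a (dendritic cells), Pf4 and Ppbp (erythroid cells and platelets), and Krt18, Col1a2, Krt8, Col1a1, Pdgfra and Kdr (stromal, endothelial and epithelial cells). After the data were seen, 10 members known in T cells were left out (Ighm, Cd72, Cd74, Bst2, Ccr9, Txk, Xbp1, Pecam1, Ccl5 and Nkg7). Of the 9 lists, 8 then had a median under 1 TPM. Leaving out high members lowers a median by itself, so this count is no test of how pure the cells were.

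The sex-linked genes went with the male label. The Y-linked genes Eif2s3y (125.3 ± 4.01 TPM), Ddx3y (70.2 ± 3.27 TPM), Uty (49.2 ± 0.30 TPM) and Kdm5d (26.6 ± 4.25 TPM) were detected, and Xist stood at 0.555 ± 0.049 TPM and Tsix at 0.66 ± 0.16 TPM. All 12 housekeeping genes were detected, at a median of 748.2 ± 0.94 TPM.

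T cell receptor transcripts were spread over many V segments. All 22 Trbv segments had reads, from totals of 13393 and 11645 counts, and their effective number (the exponential of the Shannon entropy) was 16.9 and 16.6. Trbv13-2 (chromosome 6, 41121396 to 41121832) took 9.67% of Trbv counts in technical replicate 1 (95% Clopper-Pearson interval 9.17 to 10.2) and 9.98% in technical replicate 2 (9.44 to 10.5). Trbv3 took 9.04% and 9.68%, and Trbv19 9.09% and 9.18%. Among 108 Trav segments with totals of 8170 and 7245 counts, Trav7-4 (5.91% and 5.36%), Trav7d-4 (2.57% and 3.75%) and Trav12n-3 (2.53% and 2.95%) had the highest mean shares as single segments. In technical replicate 1 alone, Trav7-2 (3.32%) and Trav9-1 (2.74%) exceeded Trav7d-4 and Trav12n-3, and in technical replicate 2 Trav7d-2 (2.97%) exceeded Trav12n-3. The Trav locus holds near-identical copies, so shares of single Trav segments are uncertain. The constant genes Trac, Trbc2 and Trbc1 stood at 2998 ± 48.0, 3764 ± 55.1 and 1983 ± 48.0 TPM, against 21.8 ± 4.39 TPM for Tcrg-C1 and 1.66 ± 0.15 TPM for Trdc. By TPM in place of counts, the share of Trbv13-2 was 11.7%.

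**Figure D2:**
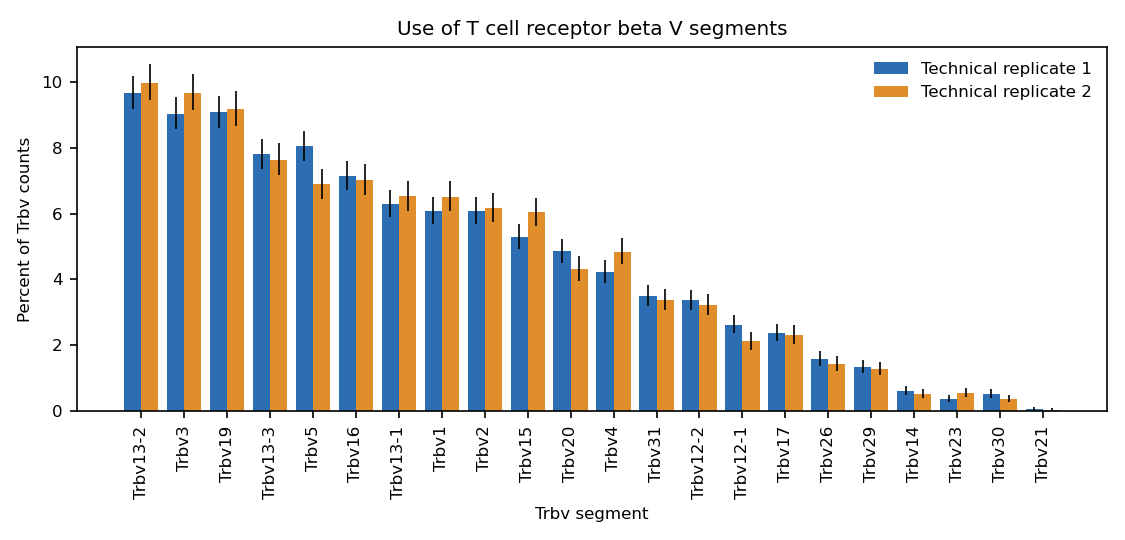
Bars give the percent of all Trbv counts taken by each segment in technical replicate 1 (blue) and 2 (orange), with 95% Clopper-Pearson intervals as lines. The highest share was that of Trbv13-2, at 9.67% and 9.98%, and the lowest that of Trbv21, at 0.067% and 0.026%.

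Isoform shares were examined in 12 genes fixed beforehand. A single transcript held at least 50% of the gene's TPM in both libraries for 8 of them. These were Ctla4-201 (98.2% ± 0.42), Tcf7-201 (98.0% ± 0.27), Tnfrsf1b-201 (89.9% ± 7.04), Lef1-203 (87.0% ± 2.38), Foxp3-207 (81.4% ± 0.96), Il2ra-201 (75.0% ± 1.27), Cd44-207 (63.4% ± 0.028) and Ikzf2-205 (62.3% ± 0.97). Foxp3-207 is annotated as subject to nonsense-mediated decay and Ikzf2-205 as a retained intron. Shares of TPM are scaled by transcript length. By estimated counts the longer, protein-coding Ikzf2-201 held more (14722 and 12308) than Ikzf2-205 (6189 and 5342). Of Foxp3 counts, 1.04% and 9.05% were assigned to the 4 transcripts that end within 50 nt of the distal end of the annotated 3′ UTR at position 7595245. Entpd1-204 (43.3% ± 1.36), Runx1-207 (43.6% ± 4.92) and Ptprc-203 (38.7% ± 1.57) led their genes with smaller shares. By estimated counts Runx1-201 (766 and 668) exceeded Runx1-207 (483 and 373). For Il1rl1, which encodes the interleukin-33 receptor, the leading transcript changed with the library. Il1rl1-202 held 68.9% in technical replicate 1 and 11.2% in technical replicate 2, against 0% and 77.1% for Il1rl1-201, so its shares were not resolved.

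To measure the technical error, the libraries were compared gene by gene. Across 29554 genes, log2(TPM + 1) had a Pearson r of 0.980 and a Spearman rho of 0.861, where genes are not independent replicates. The SD of the log2 ratio fell from 1.44 for 4216 genes with a mean count of 5 to 20 to 0.089 for 177 genes above 10000. Counts differed by more than read sampling allows, with an index of dispersion of 4.98, so the libraries were not 1 set of reads deposited again. In the exact binomial test, 3328 of 17334 genes were called at an adjusted p under 0.05, 1632 higher and 1696 lower in technical replicate 2. Only 850 of the calls exceeded 2-fold. With the common dispersion fitted by edgeR, 312 genes were called. That dispersion was fitted to the same 2 libraries with an intercept only, so their difference counted as noise. Fewer calls follow from this by construction, and they are no independent check. The binomial test on the smaller gene counts called 729 of 11019 genes, with an index of dispersion of 2.54.

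Of the 20 proliferation genes 19 had a lower TPM in technical replicate 2 than in technical replicate 1, with a median log2 ratio of -0.19, at percentile 0.40 of matched random lists. The binomial test called 7 of them lower and Mcm6 higher, and adjusted over the list alone it called 10, of which 9 were lower. Among all tested genes it called 19.2%. Calls were also frequent on lists whose medians did not shift, with 8 of 18 T cell core genes (4 lower) and 11 of 14 interleukin-2 signalling genes (5 lower). Of 19 regulatory T cell identity genes, 14 had a lower TPM in technical replicate 2, and 6 were called, 5 of them lower. The mitotic cyclin gene Ccnb2 went from 10.97 to 5.16 TPM, the mitotic kinase gene Cdk1 from 7.87 to 5.03 TPM, the topoisomerase gene Top2a from 26.0 to 19.5 TPM, and the proliferation marker gene Mki67 from 7.19 to 4.01 TPM. In estimated counts, before adjustment for library size, Cdk1 went from 95 to 43, Top2a from 1078 to 616 and Mki67 from 521 to 367. The size of these falls thus differed between TPM and counts. With the edgeR dispersion, Ccnb2 was the only proliferation gene called, and Igkc, Jchain, C1qb and Krt18 were called on other lists. B cell genes had a median log2 ratio of -0.35 (percentile 0.09), and the antibody light chain gene Igkc went from 614 to 182 counts. The plasma cell list, with a median of -0.11 at percentile 15.3, lay inside the central 95%, but outside it with a pseudocount of 0.1 (-0.83, percentile 1.55). Immediate early genes (median 0.11, percentile 97.9) and NK cell genes (0.30, percentile 98.2) lay at the other end by their medians. The test called 3 of 13 B cell genes, all lower, 4 immediate early genes higher and 4 lower, and 0 of 5 NK cell genes. With ratios of counts per effective library size, of these 4 lists the proliferation list alone stayed outside the central 95% of matched random lists (-0.32, percentile 0.01). The others lay just inside, the B cell list at -0.26 (percentile 2.70), the immediate early list at 0.10 (percentile 97.3) and the NK cell list at 0.61 (percentile 97.47). The median log2 ratio was 0.01 for the T cell core and -0.05 for regulatory T cell identity genes, at percentiles 79.6 and 12.8. In the smaller table at 10 or more counts, an alternative chosen after the data were seen, the T cell core (0.08, percentile 99.5) and interleukin-2 signalling genes (0.11, percentile 98.5) lay above the central 95%. Counts of abundant genes levelled off there, as for Trac (1167 and 1139 counts, but a log2 ratio of -0.029 in the larger table). Near-equal counts give a ratio above 0, because technical replicate 2 had the lower total. The smaller table therefore does not settle whether these lists shifted.

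The genes with the largest called ratios included V segments and near-identical copies. Jchain, which joins antibody units, was lower in technical replicate 2 (171 and 18 counts, log2 ratio -3.04, 95% interval -3.86 to -2.37), and so was the light chain segment Igkv14-111 (205 and 3 counts, -5.70, -8.21 to -4.35). Trav7-2 was lower (-4.26) and its copy Trav7d-2, with 0 counts in technical replicate 1, was higher. Its ratio was 81.0-fold if 3 counts are taken there, and the lower end of its 95% interval was 6.03 in log2. The summed counts of Trav7-2 and Trav7d-2 were 270.7 and 226.9. The pseudogenes Gm1972 and Gm16531 changed in opposite directions with sums of 113.0 and 112.6 counts. A gene named Nnt (ENSMUSG00000116207) was higher (5.11), yet it overlaps a second Nnt gene, and their summed counts were 710 and 579. Gm14288 (1.92) and Gm28042 (1.90) were also higher. Rpl7a-ps11, with 0 counts in technical replicate 2, was lower, 34.5-fold if 3 counts are taken there. The upper end of its 95% interval was -4.79 in log2.

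**Figure D3:**
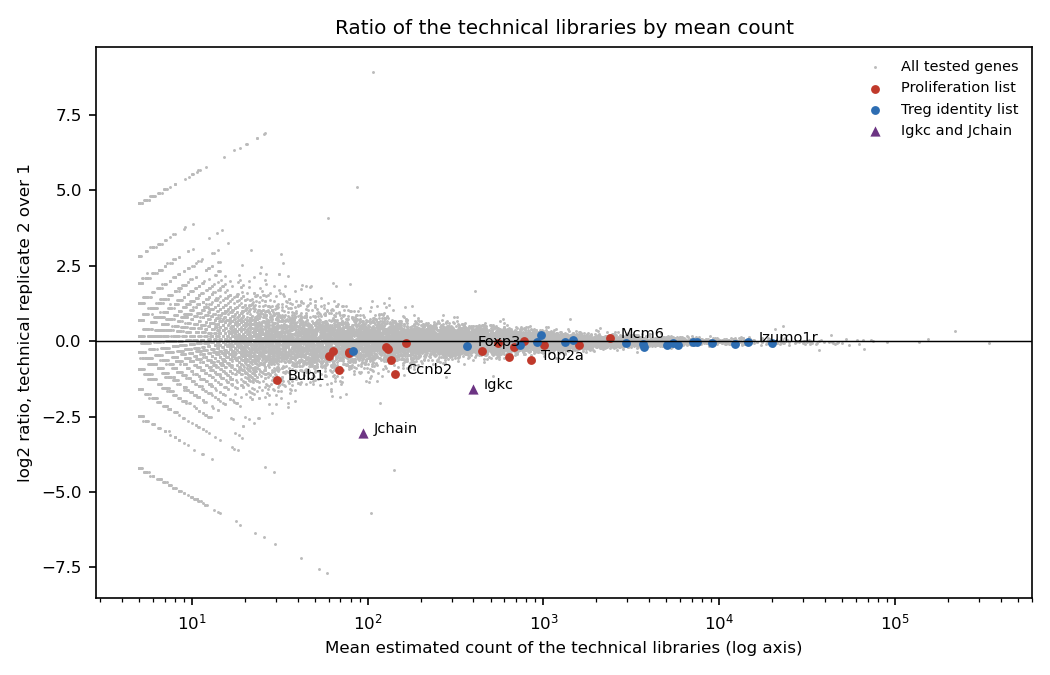
Each point is a gene with at least 10 counts, with the mean estimated count of the technical libraries (log axis) against the log2 ratio of technical replicate 2 over 1. The ratio drawn is that of counts per effective library size. Proliferation genes (red) lie mostly below 0, Igkc and Jchain (purple) at -1.58 and -3.04, and regulatory T cell identity genes (blue) near 0. The median of -0.19 given for the proliferation genes in the text is that of the TPM ratio, which is not drawn.

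The gene tables deposited for each library were compared to see how far a level depended on the quantification. Across genes, log2(CPM + 1) had a Pearson r of 0.909 in technical replicate 1 and 0.908 in technical replicate 2. The smaller table held 25.6% and 26.6% of the counts of the larger one over the same genes. Of 9642 genes with enough counts, 740 were discordant over 4-fold in both libraries, and 672 of them had the larger share in the larger table. The mitochondrial genes mt-Co3, mt-Atp6 and mt-Co2 had 0 counts in the smaller table, against 76135, 42602 and 36231 estimated counts in technical replicate 1 of the larger one. Conversely, Trbj1-2, Ece2 and G530012D18Rik had 0 counts in the larger table, against 102, 139 and 145 in the smaller one. Counts of abundant genes levelled off in the smaller table, where the highest count was 7093 in technical replicate 1, against 372456 in the larger table. At a 2-fold threshold 4061 genes were discordant.

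**Figure D4:**
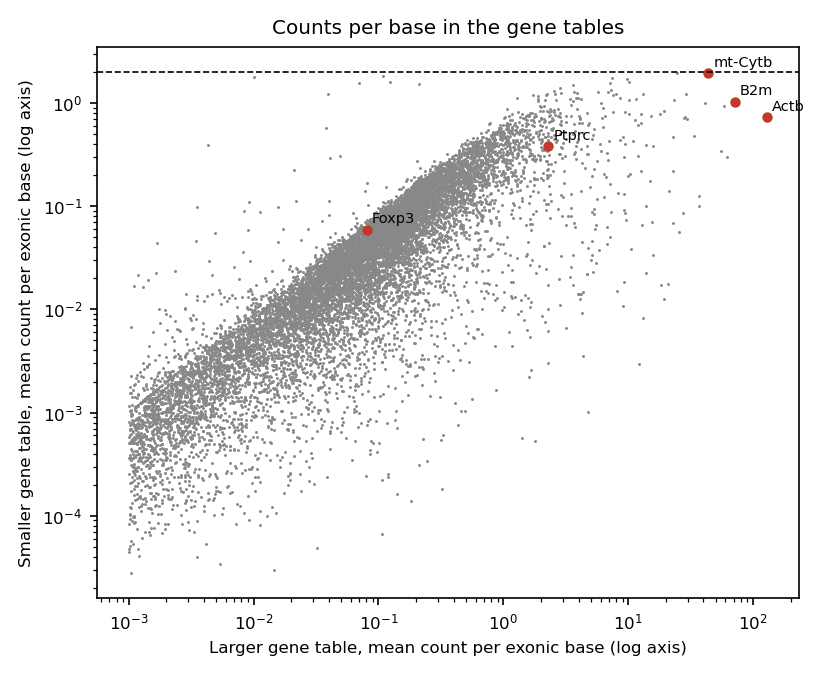
Each point is a gene with reads in both gene tables and at least 0.001 counts per exonic base in the larger one. Axes give the mean count per exonic base over the technical libraries in the larger (horizontal) and smaller table (vertical), both log axes. No plotted gene lies above 2 counts per base in the smaller table (dashed line), and mt-Cytb reaches 1.97.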

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

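Reads on entries outside the gene comparisons exceeded the limit of 3 counts that a count of 0 allows. The phiX174 genome, a bacteriophage widely used as a sequencing control, took 24124 counts in technical replicate 1 and 19308 in technical replicate 2. The transfer RNA entries took 2627 and 2288 estimated counts. No sample without such reads was analysed here, and no explanation was tested.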

How the results depend on the processing

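Among the main counts and values, 33 alternatives kept the count within 1.5 times or the value within its spread and 17 did not, and the cause was not tested unless the alternative removed genes or members. Expressed genes stayed between 9391 and 18888 in every alternative run, and isoform counts between 8 and 9. Random lists from genes at 1 TPM or more left 8 lists above the central 95% of random lists, against 14. Lists of other cell types with a median under 1 TPM numbered 5; judged by their highest member there was 1, at a threshold of 5 TPM 9, and without members known in T cells, a choice made after seeing the data, 8. Genes called between the libraries numbered 3328 (19.2% of those tested), but 312 (1.80%) with the edgeR dispersion, 1648 (18.3%) among genes with whole counts, where fewer were tested, 729 (6.62%) in the smaller table and, chosen after seeing the data, 374 (5.80%) among its genes under 0.1 counts per base. Pearson r was 0.936 with a pseudocount of 0.1, 0.988 for genes at 1 TPM or more and 0.986 in the smaller table. The index of dispersion was 2.54 in the smaller table and 2.48 under 0.1 counts per base. Of 4 shifted lists, 1 remained outside the percentiles with counts per effective library size and 1 in the smaller table at 10 to 100 counts, where the immediate early list reversed to -0.14 over 3 members. With a pseudocount of 0.1, 5 lists lay outside, and in the smaller table at 10 or more counts 4 did, 2 of them among the 4 shifted lists. The share of Trbv13-2 was 11.7% by TPM, and 4061 genes were discordant at 2-fold. Of the values of single lists, transcripts and segments, 217 kept their side or stayed within the spread, 67 moved, 7 weakened and 3 strengthened. Leaving out either library changed no main count by over 1.5 times. No paired analysis was possible because the labels gave 1 group. For genes of 5 to 20 mean counts the SD of the log2 ratio was 1.44, against 0.868 from counting alone, so depth limited them only in part.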

Other observations

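Of the globin genes, Hba-a2 reached 9.70 ± 1.78 TPM and Hbb-bs 7.74 ± 0.59 TPM, and the platelet gene Pf4 stood at 0.11 ± 0.16 TPM. Among lineage-defining factors of helper T cells, Gata3 stood at 108.4 ± 11.0 TPM and Tbx21 at 2.79 ± 0.35 TPM. These genes were chosen after their values were seen.

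The tests of unstable transcript assignment, of a single read per position, of proliferation genes in the smaller table, of the size of the GC and length trend, and of genes above 2 counts per base were chosen after the result was seen. The median log2 ratio of the proliferation list lay below 0 although both libraries came from the same biological replicate, with 7 of 20 genes called lower in technical replicate 2 and 1 higher, and Ccnb2 alone called with the edgeR dispersion. Among all tested genes the binomial test called 19.2%. A trend of the log2 ratio with GC content and gene length is argued against as the whole cause, since the fitted trend (0.573% of the variance over 17323 genes) lay between -0.024 and 0.033 of its median over genes for the 20 members, against a list median of -0.19, and the list stayed at percentile 0.48 after its removal. Noise that acts on each gene on its own is argued against as the whole cause, since 19 of the 20 members had a lower TPM in technical replicate 2. By counts per effective library size the list lay at percentile 0.01 of matched random lists. Its percentile of 0.40 by TPM would not show this alone, because the list was picked from 24. The smaller table, where the list lay at percentile 0.01 (median -0.25), counts the same libraries again and would carry the same noise, so it cannot decide this. A different share of cycling cells in the RNA of the libraries may remain as a candidate explanation that was not tested, and no biological explanation was tested because the labels gave 1 group.

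Foxp3 reads were assigned mostly to transcripts that end at least 1446 nt before the distal 3′ UTR end. Unstable assignment of reads between transcripts stays open, since the distal share was 1.04% and 9.05% of the estimated counts in technical replicates 1 and 2 and 1.90% and 5.39% by the posterior estimate, and a low share does not show that the assignment was right. Loss of distal signal in all genes is argued against, a reading made after the values were seen. The median of 8216 genes with ends at least 1000 nt apart had 81.8% and 81.7% of its counts in distal transcripts. Ends were compared by genome position, introns included, so this is no measure of 3′ UTR alone. The Foxp3 share lay at percentile 4.62 of these genes in technical replicate 1 but at percentile 11.4 in technical replicate 2. With the limit set at percentile 10, whether Foxp3 was unusual among them stays open. The engineered Foxp3 allele named in the labels could also remove distal sequence, and this stays open because 0 libraries of mice without the allele were analysed here. No biological explanation was tested.

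Counts of abundant genes levelled off in the smaller table. Removal of reads that map to several places is argued against as the whole cause, because among genes with whole counts the median ratio of the larger to the smaller table was 9.01 times as high at 10 or more reads per exonic base (12 genes, 11 with a ratio, from 9.40 to 158.0) as at 0.1 to 1. Keeping 1 read per start position and strand may explain a ceiling near 2 counts per base. Of 57 genes at 10 or more reads per base, 0 exceeded it and the highest, mt-Cytb, reached 1.97, but the 95th percentile was 1.31, under the 1.5 set for this explanation, so it stays open. Over all genes 4 exceeded 2 counts per base (Trbd2, Trbd1, Trbj2-7 and Trbj1-2), each of at most 48 exonic bases and with 0 counts in the larger table, and no biological explanation was tested.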
